A study of Mus musculus with 12 samples.

How the data were processed

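Polyadenylated RNA of the left ventricle apex was measured in 12 libraries, 3 for each of 4 groups formed by genotype (Trp53cor1 knockout or heterozygous control) and surgery (sham or TAC), 8 weeks after surgery. Per the labels, total RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. Reads were aligned to GRCm38.p6 with STAR and counted with featureCounts, and SAMtools is also named; tool versions, the annotation, the strand setting and the normalisation tool are not given in the sources used here.

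The deposited table holds signal values that the authors made by dividing the reads per gene by one size factor per library. This was read from the values themselves. All values of a column are whole multiples of one step (100% within 0.01), so whole reads could be recovered, and the factors equal median-of-ratios size factors of those reads (largest difference 9.3e-12). The table has 56350 Ensembl gene IDs, of which 55480 matched GENCODE M21, 55180 with the same version. The 870 without a match held 0.0013% of reads, and 114 symbols were shared by several IDs. All 12 columns matched a sample. Recovered reads numbered from 10323605 to 13238934 per library. A count of 0 was read as up to 3 counts.

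Genes with a value of at least 10 in at least 3 libraries were tested, 13916 in number. limma-trend (limma 3.58.1 in R 4.3.3, with robust moderation) was fitted to log2(value + 1) with 4 group means and all 12 libraries, and 5 contrasts were tested with Benjamini-Hochberg adjustment at 0.05 within each contrast. The contrasts were TAC against sham in controls and in knockouts, knockout against control after sham and after TAC, and the difference of the TAC effects (interaction). The samples, contrasts, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. That plan assumed counts and an edgeR test and named limma-trend for a table without counts; since the deposited values are normalised, limma-trend was used, and the count tests on recovered reads became alternatives.

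The rule named Trp53cor1 and Cdkn1a in every comparison. It also named, per contrast, the 8 highest and 8 lowest changes among genes that passed, had a mean of at least 1 CPM and no overlap between the libraries of both groups (no such condition for the interaction), leaving predicted genes unnamed. Where fewer than 5 genes passed, the 5 with the smallest p were named. Up to 4 members of each described list with the smallest p and a fixed set of 18 heart genes completed it; Tnnt1, Cox7a1 and other list members are covered by these parts, and Tnnt1 in the TAC comparison of controls and the values of Nlrc3 in controls were added after their values were seen. Some genes that the rule named, with their results under other settings, are not reported here.

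Of 34 gene lists 33 were tested and the sex-linked list served as a check of the libraries. The lists were tested with camera on the same values with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 165 tests, and again with an estimated correlation and with fry. fry asks whether members move one way on balance and does not compare a list with other genes. Trp53cor1 and Cdkn1a were also compared by two-sided exact permutation tests of the genotype over 12 libraries and within sham and TAC (6 tests). Transcript length and GC content came from GENCODE M21 and were known for 99.9% of tested genes; their trend was removed from each library by loess (span 0.5) in an alternative. Expected correlations came from 100 simulations with no effect.

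The fit was tested on simulated data with counts and library sizes like these, in which each gene varied independently of the others. In the TAC comparison of controls it called 26.9%, 60.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, and 11 of 13708 unchanged genes. For the difference of TAC effects the shares were 7.46%, 27.3% and 83.3%. A simulated length trend led to 813 calls among 13753 unchanged genes in the TAC comparison of controls, and 5 after the trend was removed. A list of 30 changed genes was called by camera, with an estimated correlation and by fry in each comparison. Members of real lists can vary together within groups. Their mean correlation ran from −0.062 for atrial markers to 0.845 for mitochondrially encoded genes. These simulated shares and calls therefore do not show how the tests fare on genes that vary together.

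Alternatives were edgeR 4.0.16 quasi-likelihood tests, DESeq2 1.42.0, voom with quality weights, other scalings and filters, pseudocounts of 0.5 and 5, the replicate number as a block, the libraries compared alone, the removal of the length and GC trend, and leaving out each library in turn. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Libraries of one group differed by a chi-square of 5.55 to 59.1 per gene, more than counting alone gives, and no pair was identical. Y-linked genes summed to between 1106 and 2302 and Xist lay between 0 and 5.79 in the 12 libraries.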

Results

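Polyadenylated RNA from the apex of the mouse left ventricle was sequenced 8 weeks after sham surgery or transverse aortic constriction (TAC), a narrowing of the aortic arch that loads the left ventricle with pressure. Mice lacking lincRNA-p21 (gene symbol Trp53cor1), a long noncoding RNA induced by p53, were set against littermates that the labels give as heterozygous, called controls here. The 4 groups, control sham, control TAC, knockout sham and knockout TAC, held 3 libraries each. Reads assigned to genes numbered from 10323605 to 13238934 per library. Values are normalised read counts (reads divided by one size factor per library), given as mean ± SD with n = 3 unless another error is named. Changes are differences of log2(value + 1) ± SE, a scale that understates the change of genes with low counts. Control sham replicate 3 stood apart from the other 11 libraries on the second principal component (score −46.8, with 14.4% of the variance) and had the smallest share of mitochondrial reads, 12.5% against up to 19.99% in the other libraries. Overlapping, antisense and paralogous genes are uncertain, since the strand setting used in counting is not stated. The labels do not name the animals, so p-values measure the spread between samples.

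Trp53cor1 (ENSMUSG00000085912.2, a lincRNA on GRCm38 chromosome 17, 29057430 to 29079179) was detected at a very low level in controls and in no knockout library. The control sham libraries held 2, 0 and 2 reads and the control TAC libraries 4, 0 and 3 reads. Together the 6 control libraries held 11 reads of 69704245, or 0.158 CPM (counts scaled to library size), and 4 of the 6 had a read. The 6 knockout libraries held 0 reads of 72710005, which allows up to 0.0413 CPM (3 counts over the group). This floor lies 3.82-fold under the level measured in controls, a ratio that leaves out the counting error of the 11 control reads. Such floors cover counting error only. The two-sided exact permutation test over the 12 libraries gave p = 0.0606 (adjusted over 6 tests, 0.182), and within sham and within TAC p was 0.4 each, where 3 against 3 libraries cannot go below 0.1. At this depth 2 control libraries also had 0 reads, so a single library cannot be assigned to a genotype. Cdkn1a (ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727), the neighbouring gene that encodes the cell cycle inhibitor p21, was at 584 ± 314 in the 6 controls and 272 ± 22.9 in the 6 knockouts, with overlapping ranges of 135 to 1041 and 236 to 300.1. The two-sided exact permutation p for Cdkn1a was 0.0476 over 12 libraries (adjusted, 0.182), 0.1 within sham (adjusted, 0.2) and 0.4 within TAC (adjusted, 0.4). The part of the gene that was deleted is not in the labels.

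The comparison of TAC with sham in controls asks what pressure overload did to the ventricle of mice that carry lincRNA-p21. Many genes of the fetal and hypertrophic programme and of the extracellular matrix rose, and most nuclear genes of oxidative phosphorylation fell. By camera 13 lists passed, and 0 with an estimated correlation. Thbs4 (ENSMUSG00000021702.7, chromosome 13, 92751590 to 92794818), a matricellular thrombospondin, rose from 62.4 ± 2.95 to 982 ± 199.5, a change of 3.94 ± 0.22 (limma-trend, adjusted p = 3.2e-08). Dio2, the deiodinase that activates thyroid hormone, rose from 9.89 ± 3.26 to 220.0 ± 33.4 (4.38 ± 0.38, adjusted p = 4.0e-06). Sln, an inhibitor of the sarcoplasmic calcium pump, rose by 4.25 ± 0.68, the growth factor Fgf6 by 4.25 ± 0.58, and the collagens Col12a1 and Col8a2 by 4.19 ± 0.52 and 3.85 ± 0.55. The genes that fell most were Upk3b (−3.56 ± 0.63), Muc16 (−3.52 ± 0.77), Msln (−3.51 ± 0.84), Lrrn4 (−3.18 ± 0.75) and Krt19 (−3.10 ± 0.77), all members of the mesothelial marker list, followed by Ankrd63 (−2.36 ± 0.77), the small nuclear RNA Rn7sk (−2.10 ± 0.30) and Gpr37l1 (−2.09 ± 0.51). Rn7sk went from 376 ± 57.4 to 94.2 ± 42.7. The adjusted p of Msln was 0.0611 without control sham replicate 3, that of Krt19 was 0.0520 without control TAC replicate 2, and Ankrd63 kept its call only without knockout sham replicate 1, control TAC replicate 1 or 3 or knockout TAC replicate 1 (highest adjusted p elsewhere 0.149). Ankrd63 did not pass with the length and GC trend of each library removed (−2.23, adjusted p = 0.096).

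The hypertrophy and fetal gene list rose with TAC in controls (median 1.59 over 24 measured members, camera adjusted p = 1.0e-11). Of its members 18 rose, 1 fell and 5 did not pass over all genes, and 18 rose and 1 fell when adjusted over the list alone. The list's adjusted p = 0.54 with an estimated correlation, and fry gave 0.00074. Myh7 (ENSMUSG00000053093.16, chromosome 14, 54970684 to 54994626), the beta myosin heavy chain of the fetal heart, rose from 3664 ± 1111 to 41990 ± 15464 (3.50 ± 0.26, adjusted p = 3.4e-06). Acta1, skeletal alpha-actin, rose by 4.11 ± 0.37, the titin-binding stress gene Ankrd1 by 2.53 ± 0.19, the Z-disc gene Xirp2 by 2.61 ± 0.21 and the actin regulator Enah by 1.60 ± 0.15. Nppa and Nppb, the natriuretic peptides, rose by 2.91 ± 0.42 and 1.70 ± 0.49, and Rcan1, a calcineurin regulator, by 1.84 ± 0.32. Tnnt1, slow skeletal troponin T, fell (−1.54). Myh6, the adult alpha myosin heavy chain, differed by 0.06 ± 0.16 and did not pass (adjusted p = 0.83). The Nppb call was lost without control sham replicate 1 or 2 or control TAC replicate 1 or 2 (highest adjusted p 0.0933).

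The extracellular matrix and activated fibroblast list also rose (median 0.89, 58 members, camera adjusted p = 2.7e-20), with 37 members up, 0 down and 21 not passed over all genes, and 43 up and 0 down adjusted over the list alone. Its adjusted p = 0.54 with an estimated correlation, and fry gave 0.00074. Comp (ENSMUSG00000031849.9, chromosome 8, 70373558 to 70382066), cartilage oligomeric matrix protein, rose from 46.3 ± 15.8 to 460.3 ± 84.8 (3.32 ± 0.28, adjusted p = 3.4e-06). Cilp, a matrix protein that binds TGF-beta, rose from 129 ± 6.73 to 1912 ± 386 (3.85 ± 0.28), and Ltbp2, which belongs to the TGF-beta binding proteins, by 3.42 ± 0.30. Postn, periostin of activated fibroblasts, rose by 2.51 ± 0.23, Spp1 (osteopontin) by 3.30 ± 0.58, the protease inhibitor Timp1 by 1.74 ± 0.41 and Ccn2 by 2.11 ± 0.54. Among the fibrillar collagens Col3a1 rose by 0.52 ± 0.15, while Col1a1 differed by 0.34 ± 0.15 (adjusted p = 0.11). Calls ended without control TAC replicate 2 for Timp1 (0.0516), Col3a1 (0.106) and Ccn2, for Col3a1 also without control sham replicate 2, and for Ccn2 also without control sham replicate 3 or control TAC replicate 1 (highest adjusted p 0.0683). Col3a1 did not pass with the length and GC trend removed either (0.43, adjusted p = 0.079).

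Of 75 nuclear-encoded subunits of oxidative phosphorylation, 66 fell, 0 rose and 9 did not pass over all genes, and 68 fell and 1 rose adjusted over the list alone (median −0.73, camera adjusted p = 7.8e-28; adjusted p = 0.58 with an estimated correlation; fry 0.0098). The ATP synthase subunit Atp5d fell from 11364 ± 2311 to 5658 ± 148 (−0.99 ± 0.14), and the complex I subunit Ndufs7 (−0.99 ± 0.14) and the cytochrome oxidase subunit Cox7a1 (−1.14 ± 0.18) fell too. In fatty acid oxidation 13 of 40 genes fell and 1 rose, and 18 fell and 3 rose adjusted over the list alone (median −0.33, camera adjusted p = 1.6e-05; adjusted p = 0.58 with an estimated correlation). Ech1 (−1.17 ± 0.13), the thiolase Acaa2 (−1.07 ± 0.12) and Etfb (−1.40 ± 0.19), which carries electrons from fatty acids to the respiratory chain, fell. Ppargc1a, a coactivator of mitochondrial genes, was the member that rose (1.08 ± 0.26), a call lost without control sham replicate 3 (adjusted p = 0.0840). Cpt1b and Pdk4 differed by −0.04 and 0.20 and did not pass (adjusted p = 0.87 and 0.62). Of 23 glycolysis genes 11 fell and 1 rose, by either adjustment, the latter Pfkp (median −0.27, camera adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation). Of 24 TCA cycle genes 7 fell, and 9 adjusted over the list alone (median −0.13, camera adjusted p = 0.012; adjusted p = 0.78 with an estimated correlation). The glycolysis call ended without control sham replicate 2 (0.0509) or control TAC replicate 1 (0.0538), and the TCA cycle call without control sham replicate 1 (0.126) or 2 (0.173). The glycolysis call also ended with the length and GC trend removed (median 0.03, adjusted p = 0.31, 3 down and 0 up), and there Ppargc1a (0.65, adjusted p = 0.13) and Pfkp (0.55, 0.11) did not pass.

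Marker genes of other cell types moved with the same comparison. The mesothelial markers fell (median −1.73, 14 members, camera adjusted p = 0.00012; adjusted p = 0.58 with an estimated correlation), 7 over all genes and 9 adjusted over the list alone, with Upk3b at 135 ± 68.1 after sham and 11.1 ± 9.09 after TAC. The erythroid markers fell (median −1.005, 7 members, camera adjusted p = 0.0019; adjusted p = 0.58 with an estimated correlation), 3 over all genes and 6 adjusted over the list alone, among them the heme synthesis gene Alas2 (−1.005 ± 0.25). The endothelial markers fell (median −0.44, 22 members, camera adjusted p = 0.00013; adjusted p = 0.58 with an estimated correlation), 4 over all genes and 8 adjusted over the list alone. With the length and GC trend removed the erythroid median was −0.67 with 0 members passing over all genes (Alas2 at −0.78, adjusted p = 0.069), and 2 endothelial members passed. Of the atrial cardiomyocyte markers 5 of 12 rose and 2 fell over all genes, and 5 rose and 4 fell adjusted over the list alone. The atrial light chain Myl4 rose by 2.59 ± 0.31 and Dkk3 by 2.11 ± 0.33, Sln and Nppa rose as given, and Stard10 fell (−1.34 ± 0.16). The list's median was 0.06 and its mean 0.76; camera did not call it (adjusted p = 0.46) and fry called it up (0.00074).

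In all, 3006 of 13916 genes passed in controls, 1533 up and 1473 down, of which 193 are predicted genes. The changes followed transcript length across genes (Spearman rho 0.409), with a median of −0.41 among 798 genes under 1 kb and 0.49 among 794 genes over 8 kb, and they followed GC content (rho −0.437). The 3 control TAC libraries had rho between 0.326 and 0.409 for length, the other 9 between −0.343 and 0.148. With the length and GC trend of each library removed, a step chosen after the trend was seen, 1358 genes passed, 1071 of them among the 3006. The counts by list were then 18 up and 1 down for hypertrophy, 39 up and 0 down for matrix, 0 up and 49 down for oxidative phosphorylation and 0 up and 9 down for fatty acid oxidation. Leaving out control TAC replicate 1 gave 1934 genes and leaving out replicate 2 gave 1549.

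**Figure D1:**
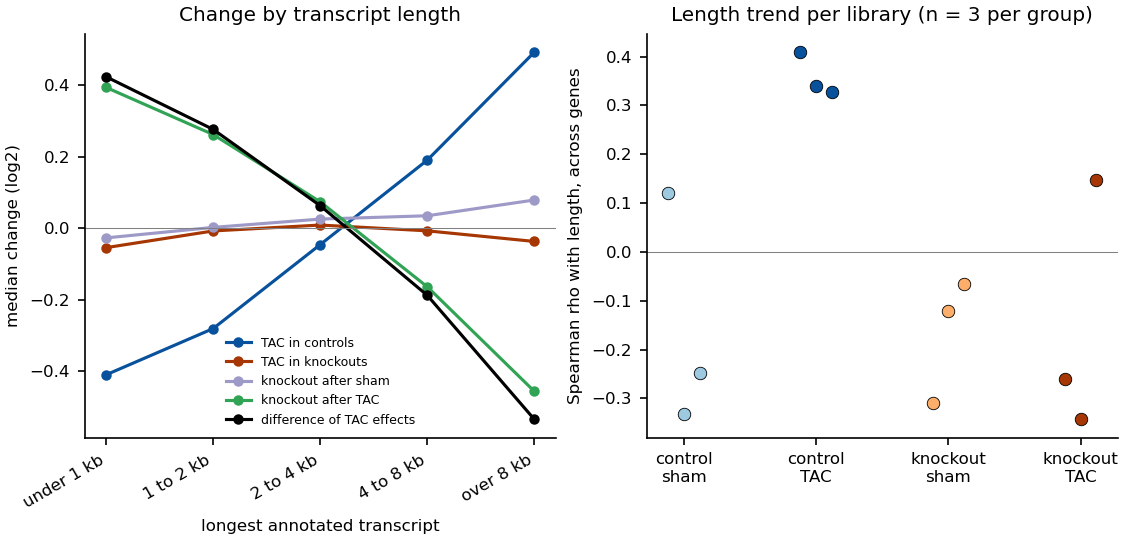
Left, median change (log2, vertical axis) of genes grouped by transcript length (horizontal axis, kb) for each comparison, without removal of the length and GC trend. Right, Spearman rho with transcript length across genes (vertical axis) in each library, by group (horizontal axis). In the TAC comparison of controls the median goes from −0.41 under 1 kb to 0.49 over 8 kb before removal.

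The comparison of TAC with sham in knockouts asks for the response to overload without lincRNA-p21. In these libraries 1 gene passed, Nlrc3, a regulator of innate immune signalling, which rose from 25.1 ± 1.28 to 102 ± 16.7 (1.96 ± 0.23, limma-trend adjusted p = 0.0034). Nlrc3 also rose from 30.8 ± 8.06 to 328 ± 77.6 in controls. The genes with the next smallest p did not pass: Edn3, an endothelin (2.11 ± 0.36, adjusted p = 0.16), Ankrd1 (0.97 ± 0.19, 0.40), Mybpc2 (0.91 ± 0.18, 0.40) and Usp50 (−2.83 ± 0.58, 0.40). Acta1 was at 5064 ± 349 after sham and 19714 ± 9131 after TAC (1.82 ± 0.37, adjusted p = 0.41), Myh7 at 10003 ± 441 and 15713 ± 2683 (0.64 ± 0.26, 0.70), Nppa at 779 ± 31.7 and 1603 ± 366 (1.01, 0.72) and Postn at 408 ± 88.3 and 810 ± 252 (0.95 ± 0.23, 0.43). Each of these genes was lowest in replicate 3 of the knockout TAC libraries, with Acta1 at 9170 there against 24979 and 24992 in replicates 1 and 2. That library also differed from these replicates on the second principal component (score −15.6 against 22.9 and 33.7), so the group is not uniform. Col1a1 and Col3a1 differed by −0.13 and −0.10 and Cdkn1a by −0.07, and none of Nppb, Myh6, Atp2a2, Rcan1, Ccn2, Timp1, Spp1, Pdk4, Cpt1b, Ppargc1a and Gdf15 passed (adjusted p from 0.74 to 0.94). At an unadjusted p under 0.05 there were 929 genes, DESeq2 called 22 genes, and voom with quality weights called 835. The Nlrc3 call was lost without knockout TAC replicate 1 (adjusted p = 0.0646), which left 0 genes; there were 2 without control sham replicate 3, 3 without control TAC replicate 1 and 7 without knockout TAC replicate 3.

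By list, 14 of 33 lists passed camera with the preset correlation in knockouts, 9 up and 5 down, and 0 with an estimated correlation or with fry. No member of these 14 lists passed over all genes by limma-trend. The hypertrophy list rose (median 0.35, camera adjusted p = 3.3e-09; adjusted p = 0.54 with an estimated correlation), with 7 members up adjusted over the list alone. The matrix list rose (median 0.19, 1.4e-05; adjusted p = 0.58 with an estimated correlation), with 11 up adjusted over the list alone; Aspn (0.95 ± 0.23) and Bgn (0.50 ± 0.13), a pair of small proteoglycans, had small p-values within it. The interferon response list rose (median 0.37, 1.3e-09; adjusted p = 0.58 with an estimated correlation), with 37 of 38 members above 0. Fatty acid oxidation fell (median −0.19, 2.8e-07; adjusted p = 0.58 with an estimated correlation), as did calcium handling (median −0.20, 0.00020; adjusted p = 0.63 with an estimated correlation), whose median was −0.12 with the length and GC trend removed. Oxidative phosphorylation was lower (median −0.11, 0.00017; adjusted p = 0.81 with an estimated correlation), a call that ended without knockout sham replicate 1 (0.167) and without knockout TAC replicate 3, where the direction turned (0.777). For these last 4 lists 0 members passed adjusted over the list alone. Erythroid markers rose here (median 0.26, 0.043; adjusted p = 0.70 with an estimated correlation), a call that held only without knockout sham replicate 3, knockout TAC replicate 3 or a control TAC library (highest adjusted p elsewhere 0.909). Transcript length did not go with the changes in knockouts (rho −0.013), GC content did (rho −0.355).

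The comparison of knockout with control after sham asks for the effect of genotype without overload. Myh7 was at 10003 ± 441 in knockouts and 3664 ± 1111 in controls (1.498 ± 0.26) and had an adjusted p of 0.67. Epha7, an ephrin receptor (1.14 ± 0.25, adjusted p = 0.93), the phospholipid flippase Atp8a2 (0.69 ± 0.15, 0.93) and 2 predicted genes were the others with the smallest p. Cdkn1a differed by −1.01 ± 0.60, Nppb by 1.27, Acta1 by 1.06, Nppa by 0.84 and Ankrd1 by 0.61 (adjusted p = 0.93 for each), and the other genes named in every comparison had adjusted p from 0.93 to 0.99. By limma-trend 0 of 13916 genes passed, with 604 at an unadjusted p under 0.05; edgeR and voom with quality weights called 0 and DESeq2 called 1. Leaving out control TAC replicate 3 gave 1 gene. In the simulated data a 4-fold change was called for 87.9% of changed genes in this comparison and a 1.5-fold change for 20.9%. The simulated genes varied independently, and many changed genes in a comparison ease the adjusted threshold. Those shares therefore do not show which changes would have been called in these libraries.

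After sham, 14 lists passed camera, 6 up and 8 down, and 0 with an estimated correlation or fry, with 0 members passing over all genes. The hypertrophy list was higher in knockouts (median 0.23, camera adjusted p = 1.4e-05; adjusted p = 0.58 with an estimated correlation), with 1 member up adjusted over the list alone. Sarcomere genes (median 0.20, 3.4e-05) and TCA cycle genes (median 0.20, 1.4e-06) were higher, and matrix genes (median −0.17, 4.5e-07) and interferon response genes (median −0.33, 1.7e-09) lower, each with adjusted p = 0.58 with an estimated correlation and 0 members adjusted over the list alone. The endothelial markers were lower (median −0.29, 7.5e-09; adjusted p = 0.58 with an estimated correlation), with 0 of 22 members above 0, a call that ended without control sham replicate 3 (0.106), the library that stood apart. Of the 14 calls 5 held without each library in turn, those on hypertrophy, sarcomere, TCA cycle, matrix and interferon response genes.

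The comparison of knockout with control after TAC asks for the effect of genotype under overload. Many matrix genes and 4 atrial markers were lower in knockouts, and most nuclear genes of oxidative phosphorylation were higher. By camera 8 lists passed, and 0 with an estimated correlation. Thbs4 was at 94.2 ± 25.1 in knockouts and 982 ± 199.5 in controls (−3.38 ± 0.22, limma-trend adjusted p = 3.4e-07), Comp at 34.5 ± 10.98 and 460.3 ± 84.8 (−3.73 ± 0.28, 2.1e-06) and Cilp at 260.5 ± 113 and 1912 ± 386 (−2.96 ± 0.28, 9.3e-05). Col12a1 (−4.10 ± 0.52), Fmod, a collagen-binding proteoglycan (−3.42 ± 0.37), Col8a2 (−3.03 ± 0.55) and Ltbp2 (−3.02 ± 0.30) were also lower. Myl7, the atrial regulatory light chain, was at 1.71 ± 1.52 against 141 ± 62.2 (−5.84 ± 0.72, adjusted p = 0.00054), and Sln at 0.322 ± 0.557 against 45.0 ± 22.9 (adjusted p = 0.00093). Higher in knockouts were Muc16 (3.37 ± 0.77), Upk3b (2.89 ± 0.63), Rn7sk (1.87 ± 0.30), the orphan receptor Gpr19 (1.54 ± 0.39), Zfp580 (1.52 ± 0.30) and Tnnt1 (1.42 ± 0.20). Muc16 and Upk3b lost their calls without control TAC replicate 2 or knockout TAC replicate 1 or 2 (highest adjusted p 0.0934 and 0.0878). Gpr19 lost it without control TAC replicate 1, 2 or 3 or knockout TAC replicate 1 or 2 (0.0974), and with the length and GC trend removed (0.054).

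**Figure D2:**
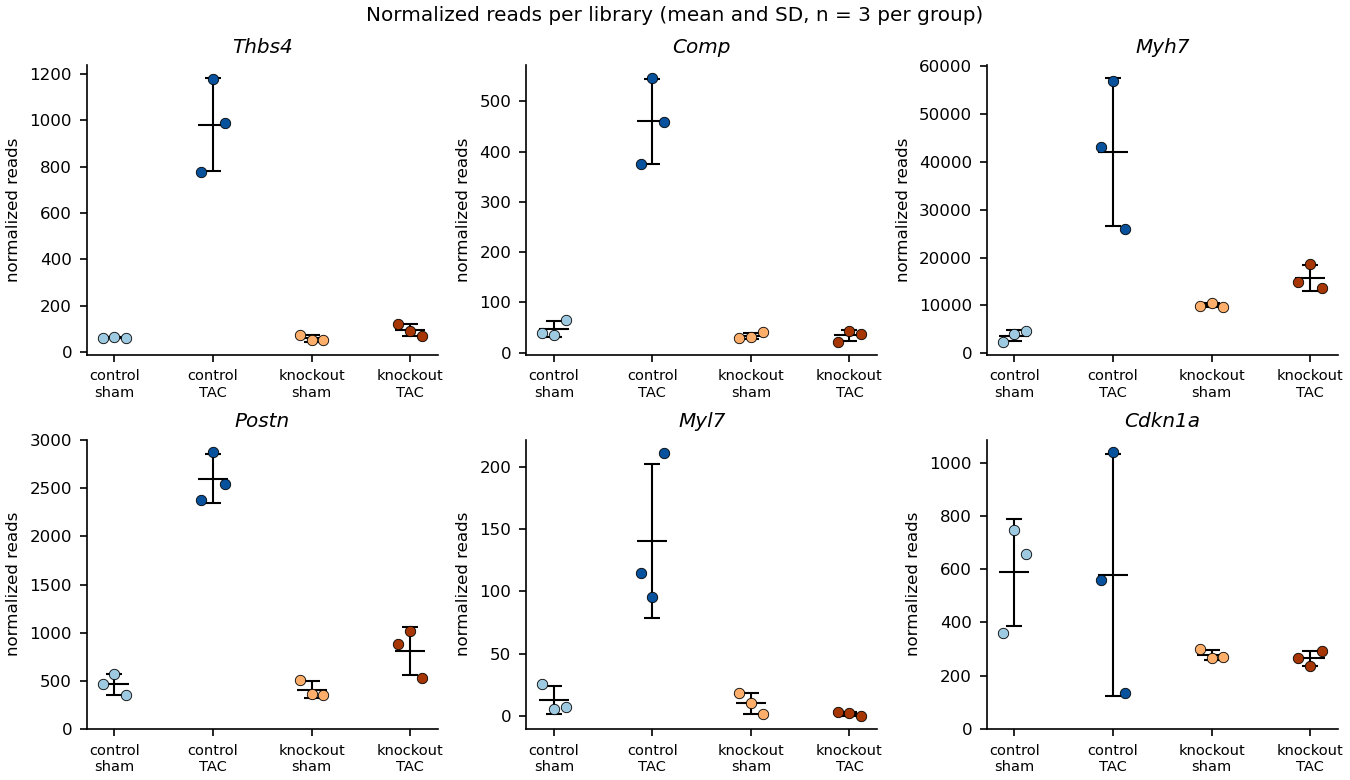
Normalised read count (vertical axis) of Thbs4, Comp, Myh7, Postn, Myl7 and Cdkn1a in each of the 12 libraries by group, with the mean and SD of each group of 3. Thbs4 has a mean of 982 in control TAC and 94.2 in knockout TAC libraries.

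The matrix list was lower in knockouts after TAC (median −0.87, 58 members, camera adjusted p = 4.9e-32), with 33 members lower, 0 higher and 25 not passed over all genes, and 44 lower and 0 higher adjusted over the list alone. Its adjusted p = 0.49 with an estimated correlation, and fry gave 0.00074. Postn (−1.73 ± 0.23), Col1a1 (−0.79 ± 0.15), Col3a1 (−0.59) and Timp1 (−1.43) were lower, while Spp1 (−1.80 ± 0.58, adjusted p = 0.061) and Ccn2 (−1.54, 0.11) did not pass. The hypertrophy list was lower (median −0.86, 24 members, camera adjusted p = 2.0e-06; adjusted p = 0.58 with an estimated correlation; fry 0.057), with 8 lower, 2 higher and 14 not passed over all genes, and 17 lower and 3 higher adjusted over the list alone. Myh7 (−1.36 ± 0.26), Ankrd1 (−0.96 ± 0.19), Xirp2 (−1.50) and Enah (−1.07) were lower. Nppa (−1.05 ± 0.42, adjusted p = 0.14), Acta1 (−1.22 ± 0.37, 0.063), Rcan1 (−0.91, 0.099), Pdk4 (−0.72, 0.11), the stress cytokine Gdf15 (−1.56, 0.17), Cdkn1a (−0.70, 0.52) and Nppb (−0.05, 0.97) did not pass, nor did Myh6 (−0.12, 0.69), Atp2a2 (−0.17, 0.66) and Cpt1b (0.19, 0.50). Col3a1 lost its call without control TAC replicate 1 or 2 or any knockout TAC library (highest adjusted p 0.116), and Ankrd1 without control TAC replicate 2 (0.0510), while Timp1 kept it only without a control sham library (highest adjusted p elsewhere 0.183). Col3a1 lost it with the length and GC trend removed too (−0.41, adjusted p = 0.15).

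Oxidative phosphorylation genes were higher in knockouts after TAC (median 0.64, 75 members, camera adjusted p = 3.7e-33; adjusted p = 0.58 with an estimated correlation; fry 0.017), with 60 higher, 0 lower and 15 not passed over all genes, and 70 higher and 1 lower adjusted over the list alone. Atp5g3, a subunit of the ATP synthase, was at 20767 in knockouts and 12605 in controls (0.71 ± 0.13, adjusted p = 0.0048). In fatty acid oxidation 11 of 40 genes were higher and 1 lower, and 18 higher and 2 lower adjusted over the list alone (median 0.33, camera adjusted p = 9.9e-06; adjusted p = 0.58 with an estimated correlation). Ech1 (0.91) and Acaa2 (0.81) were higher, and Ppargc1a (−1.16 ± 0.26) was the member that was lower. In the TCA cycle 8 of 24 genes were higher and 0 lower, and 11 adjusted over the list alone, among them Suclg1 (0.71), a subunit of succinate-CoA ligase (median 0.34, camera adjusted p = 1.7e-06; adjusted p = 0.58 with an estimated correlation). Ppargc1a lost its call without control TAC replicate 2 or knockout TAC replicate 1 or 2 (highest adjusted p 0.0991), and with the length and GC trend removed (−0.89, adjusted p = 0.069).

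The mesothelial markers (median 1.47, camera adjusted p = 0.00055; adjusted p = 0.58 with an estimated correlation) and erythroid markers (median 1.07, 7.1e-05; adjusted p = 0.58 with an estimated correlation) were higher in knockouts after TAC. Of the mesothelial genes 2 passed over all genes and 7 adjusted over the list alone, and of the erythroid genes 2 and 6. Among the atrial markers Myl4 (−2.26 ± 0.31) and Dkk3 (−2.08 ± 0.33) were lower beside Myl7 and Sln, and 4 were lower and 2 higher by either adjustment. The atrial list had a median of −0.11 and a mean of −0.996; camera did not call it (adjusted p = 0.13) and fry called it down (0.00046). In total 1145 genes differed, 570 higher and 575 lower, of which 77 are predicted genes. Scaled by library totals alone, 1252 genes differed, 299 higher and 953 lower. The differences ran with transcript length (rho −0.473), from a median of 0.39 under 1 kb to −0.46 over 8 kb. With the trend removed 538 genes differed, 420 of them among the 1145, with 27 matrix genes lower and 0 higher, 6 hypertrophy genes lower and 1 higher, and 38 oxidative phosphorylation genes higher and 0 lower (median 0.42), and 0 erythroid genes passed. The count was 2143 without control sham replicate 3, 348 and 275 without control TAC replicates 1 and 2, and 214, 202 and 1945 without knockout TAC replicates 1, 2 and 3.

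**Figure D3:**
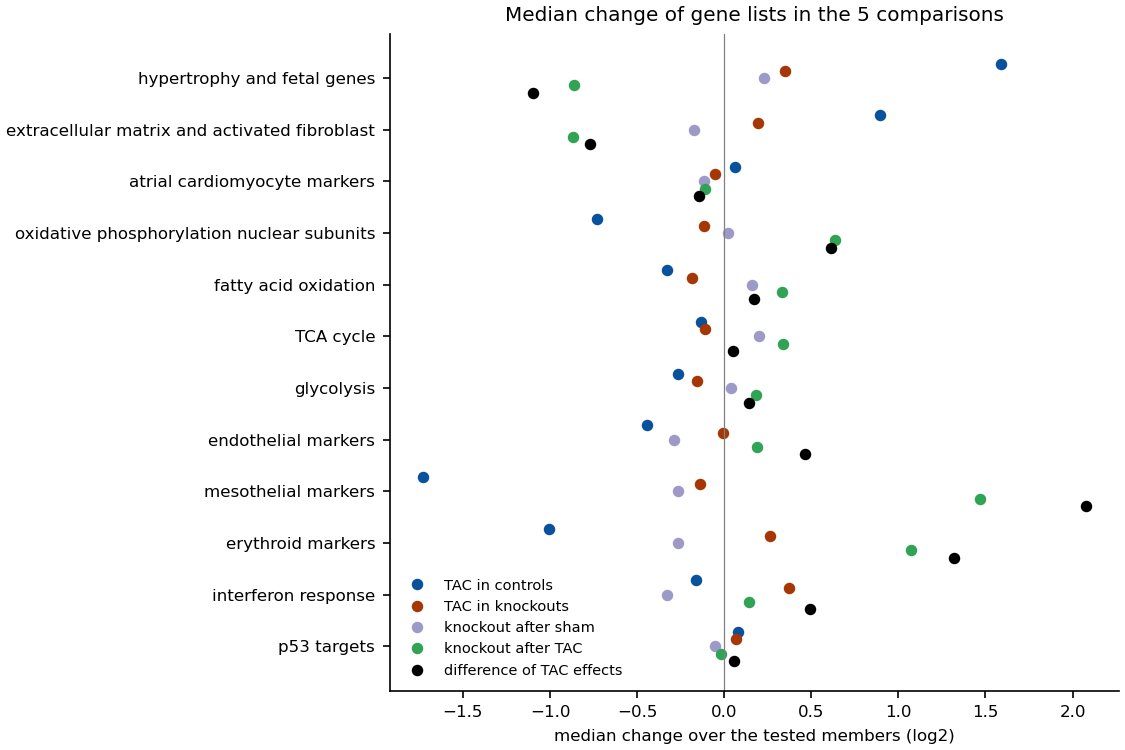
Median change (log2, horizontal axis) of the members of a selection of the tested gene lists in each comparison. Shown are the hypertrophy, matrix, atrial, oxidative phosphorylation, fatty acid oxidation, TCA cycle, glycolysis, endothelial, mesothelial, erythroid, interferon and p53 target lists. The matrix list has a median of 0.89 for TAC in controls, 0.19 for TAC in knockouts and −0.87 for knockout after TAC.

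The difference of the TAC effects between genotypes was tested directly as an interaction. Its sign is negative where the change with TAC in knockouts lay below that in controls. Thbs4 rose in controls from 62.4 to 982 and was at 58.7 ± 13.5 and 94.2 ± 25.1 in knockouts, a difference of −3.27 ± 0.31 (limma-trend, adjusted p = 0.00010). Comp (−3.31 ± 0.40, adjusted p = 0.0018), Cilp (−3.09 ± 0.40, 0.0043), Myh7 (−2.86 ± 0.37, 0.0043) and Xirp2 (−1.95 ± 0.29, 0.0096) followed, and these genes passed in every fit that left out 1 library. Part of the Myh7 difference comes from the sham groups. There Myh7 lay between 9592 and 10469 in knockouts and between 2429 and 4584 in controls, a contrast that did not pass. Further genes with a negative difference were Myl7 (−5.44 ± 1.02), Col12a1 (−4.03 ± 0.74), Angptl7 (−3.64 ± 0.74), Fmod (−3.22 ± 0.52), Dio2 (−3.18 ± 0.54), Myl4 (−2.40 ± 0.44), Ttn, the giant protein of the sarcomere (−2.16 ± 0.33), Ankrd1 (−1.57 ± 0.27) and Enah (−1.17 ± 0.21). In knockouts alone the change with TAC passed for none of these genes, and Myl7, Fmod, Angptl7 and Ttn had lower means after TAC than after sham. Hey1, a transcription factor downstream of Notch, went from 235 to 127 in controls and from 158 to 188 in knockouts (1.15 ± 0.23, adjusted p = 0.044), and Fahd2a from 461 to 269 and from 425 to 441 (0.83 ± 0.16, 0.039). Nppa (−1.90 ± 0.59, adjusted p = 0.16), Acta1 (−2.28 ± 0.52, 0.087), Postn (−1.55 ± 0.32, 0.057), Spp1 (−2.74, 0.12), Col1a1 (−0.47, 0.27) and Cdkn1a (0.31 ± 0.85, 0.89) did not pass, nor did Nppb, Myh6, Atp2a2, Rcan1, Col3a1, Ccn2, Timp1, Pdk4, Cpt1b, Ppargc1a and Gdf15 (adjusted p from 0.12 to 0.83).

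Calls on the difference were often lost with 1 library left out. Fmod lost its call without knockout sham replicate 3 or control TAC replicate 2 (highest adjusted p 0.0657), Dio2 without control TAC replicate 1 or 2 (0.0662), Ttn without control sham replicate 3 or control TAC replicate 2 (0.0636), and Ankrd1 without knockout sham replicate 2 or 3 or control TAC replicate 2 (0.0912). Others kept their calls in fewer fits. Without control sham replicate 1 or knockout TAC replicate 3 all of them passed. Col12a1 passed in 5 of 12 fits, with control sham replicate 3, control TAC replicate 3 or knockout TAC replicate 2 left out as the others (highest adjusted p 0.110). Enah passed in 5, with control sham replicate 3 or control TAC replicate 1 or 3 left out as the others (0.112), and Angptl7 in 4, with control sham replicate 3 or knockout TAC replicate 2 (0.180). Hey1, Fahd2a and Myl4 passed in 3, with control sham replicate 3 (0.174, 0.173 and 0.108), and Myl7 in 3, with knockout sham replicate 3 (0.125). The hypertrophy list differed (median −1.09, camera adjusted p = 1.9e-09; adjusted p = 0.54 with an estimated correlation; fry 0.035), with 4 members below and 0 above over all genes, and 13 below and 1 above adjusted over the list alone. The matrix list differed (median −0.77, 1.4e-18; adjusted p = 0.54 with an estimated correlation; fry 0.019), with 8 below and 0 above, and 31 below and 0 above adjusted over the list alone. Oxidative phosphorylation differed the other way (median 0.62, 4.5e-26; adjusted p = 0.58 with an estimated correlation; fry 0.091), with 0 members over all genes and 55 above and 0 below adjusted over the list alone. The mesothelial (median 2.08, 5.6e-05) and erythroid markers (median 1.32, 1.2e-05) differed too, both with adjusted p = 0.58 with an estimated correlation, 0 members over all genes, and 2 and 6 above adjusted over the list alone.

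In total the TAC change differed by genotype for 43 genes, 2 above and 41 below 0, of which 3 are predicted genes; 2292 genes had an unadjusted p under 0.05. DESeq2 called 507 genes, 228 above and 279 below 0, with 27 of them among the 43, voom with quality weights called 745 above and 831 below, and edgeR with TMM called 2 above and 33 below, so the balance of directions depends on the tool. The difference followed transcript length (rho −0.451), and with the length and GC trend removed 20 genes passed, 17 of them among the 43. The hypertrophy and matrix lists then had medians of −0.97 and −0.61, with 3 and 4 members below 0 past the test, and oxidative phosphorylation a median of 0.38. Of the genes named, Hey1 (adjusted p = 0.094), Fahd2a (0.15), Col12a1 (0.11), Angptl7 (0.070), Enah (−0.59, 0.27) and Ttn (−0.77, 0.17) then did not pass. Without control sham replicate 1, 2 or 3 the count was 755 (236 above 0), 22 or 102 (25 above). Without knockout sham replicate 2 or 3 it was 14 or 16, without control TAC replicate 1 or 2 it was 21 or 8, and without knockout TAC replicate 1, 2 or 3 it was 21, 24 or 283 (93 above).

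**Figure D4:**
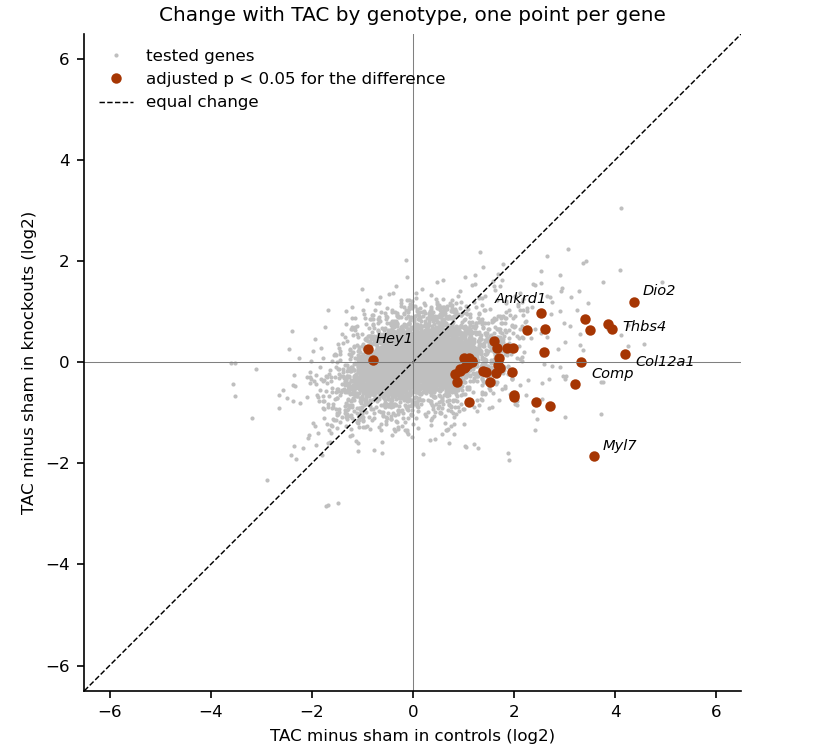
Change with TAC in knockouts (log2, vertical axis) against change with TAC in controls (log2, horizontal axis), one point per tested gene, with the 43 genes whose change differed by genotype in colour. The dashed line marks equal changes; Thbs4 lies at 3.94 in controls and 0.66 in knockouts.

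Across genes the changes with TAC in the 2 genotypes, which share no library, correlated with Pearson r = 0.362 and Spearman rho = 0.350 and a slope of 0.205; genes are not independent replicates. In 100 simulations with no effect r ranged from −0.740 to 0.842. Of the 3006 genes called in controls, 2366 (78.7%) moved the same way in knockouts, with a median of 0.14 in knockouts, signed by the direction in controls, where the median size was 0.69. The 1 gene called in both genotypes was Nlrc3. The TAC effect in controls and the knockout effect after TAC correlated with r = −0.777, but both use the control TAC libraries with opposite sign. Simulations with no effect gave a median r of −0.525, and 14 of 100 were as low. The covariance was −0.234 against −0.0488 in the simulations, a difference of −0.185, part of which may come from the shared libraries. Of the genes that rose with TAC in controls 468 were lower in knockouts after TAC, where independent lists would share 63.3, and of the genes that fell 474 were higher, where independent lists would share 60.3. The counts of genes that moved the same way in both were 0 and 0. The simulations, which share libraries in the same way, gave no opposite pairs of calls. They hold no effect of TAC, so they do not say how many pairs the shared libraries add among genes that TAC changed. The values for independent lists leave the sharing out as well. The overlaps therefore do not show by themselves that genotype moves genes against the TAC change. In 1 of the 100 simulations as many genes were called as in the data for TAC in controls (3296), in 1 for knockout after TAC (2130) and in 1 for the difference of TAC effects (280).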

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

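The tests of length, single libraries, atrial tissue and mesothelial cells and the counts over other splits of the samples were all chosen after the results were seen. The change with TAC differed between genotypes for 43 genes by a test of the difference itself. The named genes among them, with the difference in log2 (knockout minus control, negative where the change with TAC in knockouts lay below that in controls), were Hey1 (1.15), Fahd2a (0.83), Myl7 (−5.44), Col12a1 (−4.03), Angptl7 (−3.64), Comp (−3.31), Thbs4 (−3.27), Fmod (−3.22), Dio2 (−3.18), Cilp (−3.09), Myh7 (−2.86), Ankrd1 (−1.57), Xirp2 (−1.95), Enah (−1.17), Ttn (−2.16) and Myl4 (−2.40). By camera the difference also passed for the lists of hypertrophy and fetal genes (median −1.09), calcineurin, NFAT and MEF2 genes (−0.27), extracellular matrix (−0.77), endothelial (0.46), erythroid (1.32) and mesothelial markers (2.08), fatty acid oxidation (0.17), oxidative phosphorylation (0.62) and the interferon response (0.50). None of these list calls held with an estimated correlation.

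The 43 genes could owe their difference to the transcript length trend of the control TAC libraries (rho 0.326 to 0.409), and whether RNA quality, library preparation or biology gives that trend was not tested. Against that as the whole cause, 17 of them still passed with the length and GC trend removed, with a median size of 2.65 before and 2.67 after (median SE 0.37 and 0.38). For the other 26, whose median transcript length is 10036 nt, the median size fell from 1.33 to 0.782 (median SE 0.23 before and 0.21 after), and the trend stays open for them. The 17 and the 26 were set apart by the call after removal, which favours kept sizes in the first and smaller sizes in the others. The sizes therefore add no evidence to the count of genes that still passed. A single library as the whole cause is argued against for 8 genes, Thbs4, Comp, Cilp, Myh7 and Xirp2 among them, called in each of the 12 fits that left out 1 library. The other 35 kept their sign and a median size of at least 1.45 of 1.61 in each (median SE 0.25 to 0.30). All 35 lost their call without control TAC replicate 2 (1.58), and only 2 lost it in 1 fit alone. The 35 were called in these same libraries for a difference large beside its spread. That choice favours kept sizes, which are therefore weak evidence against a single library for these 35. Of 100 splits of the 12 libraries (drawn from 200, the real one among them) 4 called as many genes, and the highest other split called 261. The splits exchanged genotype within sham and within TAC. A split that mixes knockout and control TAC libraries counts their difference as spread, which can lower its count. The share of splits therefore does not decide whether chance alone gave the 43 genes. Nor does the 261 decide whether the samples hold a structure besides the groups. Simulations with no effect called up to 280 genes for this difference, and 1 of 100 called at least 43. They were built from the spread of these same libraries within groups and would carry such a structure. Whether genotype is the cause of the difference remains open.

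Some atrial markers rose in the control TAC libraries and the samples might have held atrial tissue there. Of 9 markers with a low level in sham ventricle 4 rose, Sln, Myl7, Myl4 and Dkk3, while Tbx18 (39.96 against 42.5) and Nr2f1 (36.8 against 26.3) did not pass, nor were Bmp10 (0.599 against 0), Mybphl (2.12 against 5.55) and Fgf12 (3.61 against 2.74) high enough to be tested. Of the 14 atrial markers not shared with the mesothelial list, which also holds Upk3b, these 9 lie under 100 in the sham ventricle; Clu (9139), Kcnj3 (623), Nppa (482), Stard10 (389.7) and Nr2f2 (157) are expressed there as well. The test counted only the 6 with a mean of at least 10 in control TAC libraries, a limit that a rise itself helps to meet, so it decides nothing. Atrial tissue and a change within ventricular cells cannot be told apart. Whether overload or genotype acted on these genes within ventricular cells remains open and was not tested.

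Mesothelial markers were lower in the control TAC libraries, and the share of mesothelial cells could have differed from sample to sample. Within groups the 14 markers moved together across libraries with a mean correlation of 0.466, where the highest of 1000 random lists gave 0.211 and their 95th percentile was 0.0744. Of 20 lists that mark no cell type 5 correlated as much or more, among them oxidative phosphorylation (0.584) and immediate early genes (0.669), so a varying share of cells and genes regulated together cannot be told apart by this test. Upk3b was at 135 in control sham and 11.1 in control TAC libraries. A response of these cells to overload remains open and was not tested.

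Comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. The real split is among those counted as at least as large. For genes, the real count and the highest other were 3006 and 4 for TAC in controls (1 split as large), 1 and 0 for TAC in knockouts (1 split), 0 and 0 for knockout after sham (10 splits) and 1145 and 1 for knockout after TAC (1 split). For lists they were 13 and 13 (3 splits), 14 and 14 (2 splits), 14 and 17 (2 splits) and 8 and 13 (9 splits). For the lists whose TAC change differed by genotype, 72 of 100 splits gave at least the real 9, the highest 18, so chance is not excluded for that count.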

How the results depend on the processing

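The edgeR test with TMM was the planned main test for a table of counts. Its place as an alternative was chosen after seeing the data. So were TMM scaling, pseudocounts of 0.5 and 5, and removal of the length and GC trend, while the other settings were planned. Where a value below moved, the cause was not tested, except that leaving out libraries or comparing 6 alone leaves fewer samples. The 3006 genes for TAC in controls stayed within 1.5 times except for 1358 with the trend removed and 1433 with only the 6 libraries compared, and ranged from 1549 to 3656 with 1 library left out. For TAC in knockouts (1 gene), DESeq2 called 22, voom with quality weights 835, no filter 2, the replicate block 3 and 6 libraries alone 32, with 0 to 7 when 1 library was left out. For knockout after sham (0 genes), DESeq2 called 1, with 0 to 1 when 1 library was left out. For knockout after TAC (1145 genes), voom called 3809 and trend removal left 538, with 202 to 2143 when 1 library was left out. For the difference of TAC effects (43 genes), DESeq2 called 507, voom 1576, library totals 95, no filter 124, pseudocount 5 65 and trend removal 20, with 8 to 755 when 1 library was left out. Lists called by camera (13, 14, 14, 8 and 9 in the order above) fell to 0 in each comparison with an estimated correlation and to 6, 0, 0, 3 and 3 with fry. Trend removal gave 13 lists for knockout after TAC. With 1 library left out they ranged 10 to 15, 11 to 15, 10 to 18, 7 to 10 and 8 to 12. The correlations kept their sign in all settings, r from 0.270 to 0.402 between the TAC effects and from −0.815 to −0.710 between the TAC and knockout effects, and the Trp53cor1 level (0.163 CPM as the mean of the control libraries) ranged from 0.118 to 0.196 CPM with 1 library left out.

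Libraries of different groups with the same replicate number correlated weakly if at all, and a weak shared effect of the number is not excluded. Of 18 pairs with the same number, 3 correlated above 0.1 (median 0.028, highest 0.249), and 6 of 12 libraries correlated best with one of their own number. With the number as a block, 3151, 3, 0, 1198 and 47 genes passed. The Trp53cor1 level under DESeq2 and the block was not run, since its reads per library do not depend on them. At this depth 11 reads limit what can be said of Trp53cor1, and the simulated recovery of 1.5-fold changes limits the counts of small changes.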

Other observations

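Genes of other groups changed with TAC in controls. Of 26 sarcomere genes 12 rose and 6 fell by either adjustment (median 0.28, camera adjusted p = 0.065), with Ttn (1.97 ± 0.24), Neb (3.02 ± 0.47) and Nrap (1.13 ± 0.15) up and Tnni3, cardiac troponin I, down (−0.98 ± 0.14). In knockouts against controls after TAC 6 were higher and 3 lower, and 8 and 7 adjusted over the list alone, with Ttn at −1.72 and Tnni3 at 0.78. With the length and GC trend of each library removed 9 rose and 4 fell with TAC in controls, 5 were higher and 0 lower in knockouts after TAC, and Ttn did not pass there (−0.47, adjusted p = 0.086). For TAC in controls camera then called the sarcomere list up (adjusted p = 0.011), as it did with the replicate number as a block (0.047). With an estimated correlation on the main values its adjusted p was 0.63. Of 32 calcium handling genes 7 rose and 6 fell (7 and 9 adjusted over the list alone; median −0.17, camera adjusted p = 0.58, not called), with the ryanodine receptor Ryr2 up (1.12 ± 0.23) and the potassium channel Kcnk3 down (−0.68 ± 0.12), while Atp2a2, the calcium pump, differed by 0.17 and did not pass. With the trend removed 0 calcium handling genes rose and 3 fell, and Ryr2 did not pass (0.55, adjusted p = 0.069). Of 23 calcineurin, NFAT and MEF2 genes 5 rose and 1 fell by either adjustment (median 0.20, camera adjusted p = 0.028, adjusted p = 0.58 with an estimated correlation), a call that ended without control sham replicate 2 (0.0859) or 3 (0.0519) and with the trend removed (median 0.09, adjusted p = 0.35, 1 up and 1 down). Immediate early genes (median 0.50, 0.025, adjusted p = 0.81 with an estimated correlation) had 3 members up, among them Myc (1.36 ± 0.36) and Ccn1 (0.97 ± 0.22), and 2 adjusted over the list alone. Myc lost its own call without control TAC replicate 1 or 2 (highest adjusted p 0.0692). The list call ended without control sham replicate 1 (0.340) or control TAC replicate 1 (0.137) or 2 (0.458), and with the trend removed the median was 0.81. Heat shock genes (median 0.46, 0.038, adjusted p = 0.78 with an estimated correlation) had 3 up by either adjustment, among them Hsp90aa1 (1.37 ± 0.28), a call that ended without control sham replicate 1 (0.143) or 3 (0.131), control TAC replicate 1 (0.102) or 2 (0.226) or knockout TAC replicate 3 (0.0503). Smooth muscle markers fell (median −0.43, 0.033, adjusted p = 0.58 with an estimated correlation), 4 by either adjustment, and this call ended without control sham replicate 1 (0.0595) or 3 (0.103) or control TAC replicate 1 (0.0836) or 2 (0.0761); with the trend removed the list passed with 0 members down and 1 up.

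Of 44 p53 target genes 3 rose and 6 fell with TAC in controls by either adjustment (median 0.08, camera adjusted p = 0.9998), among them the stress cytokine Gdf15 up (2.42 ± 0.68) and Mgmt, a DNA repair enzyme, down (−1.13 ± 0.23). The Gdf15 call ended without control sham replicate 1 or 3 or control TAC replicate 1 or 2 (highest adjusted p 0.0830). After TAC 4 p53 targets were higher in knockouts and 0 lower, and 7 and 2 adjusted over the list alone. Of 17 genes near Trp53cor1 2 rose and 3 fell with TAC in controls, and 2 and 4 adjusted over the list alone, with Ppil1 at −0.86 ± 0.14; camera gave 0.24, and 0.74 and 0.57 for knockout after sham and after TAC. In knockouts cell cycle genes (median 0.52, 5.6e-05), mitochondrially encoded genes (0.32, 0.0016) and integrated stress genes (0.16, 0.0028) also passed camera with TAC, upward, each with adjusted p = 0.58 with an estimated correlation, and glycolysis genes (−0.15, 0.0074; adjusted p = 0.58 with an estimated correlation) downward. Over all genes 0 members of these lists passed there, and 1 mitochondrially encoded gene rose adjusted over the list alone. With the length and GC trend removed the calls on mitochondrially encoded genes (median 0.09, adjusted p = 0.47) and glycolysis genes (−0.08, 0.0798) ended. Schwann cell and neuron markers passed downward (median −0.51, 0.010, adjusted p = 0.58 with an estimated correlation), a call that ended without knockout TAC replicate 2 (0.0687) or 3 (0.0519). Lists not called in the TAC comparison of controls were, with members up and down over all genes, T cell (0 and 2), B cell (1 and 0), neutrophil (0 and 1) and adipocyte markers (0 and 1), Schwann cell and neuron markers (0 and 3), integrated stress (6 and 1), inflammatory (2 and 2) and circadian genes (1 and 0), fibroblast (2 and 5), macrophage (0 and 1) and skeletal muscle markers (0 and 1), mitochondrially encoded genes (1 and 0), cell cycle (2 and 0), interferon response (1 and 2) and hypoxia genes (5 and 3). Adjusted over the list alone, the counts were the same for the first 6 of these and for circadian genes, and 1 and 2 for inflammatory genes, 2 and 6 for fibroblast, 0 and 0 for macrophage and 1 and 1 for skeletal muscle markers, 0 and 0 for mitochondrially encoded and cell cycle genes, 0 and 1 for interferon and 6 and 3 for hypoxia genes. With the length and GC trend removed camera called integrated stress genes up with TAC in controls (adjusted p = 0.014, 4 members up and 0 down over all genes). Their adjusted p was 0.81 with an estimated correlation on the main values. Hypoxia genes then had 1 up and 2 down, and fibroblast markers 1 and 2.

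The remaining list calls passed camera but not with an estimated correlation. After sham, the lists higher in knockouts were calcium handling (median 0.13, camera adjusted p = 0.0039; adjusted p = 0.70 with an estimated correlation), calcineurin (0.15, 0.035; adjusted p = 0.58 with an estimated correlation) and fatty acid oxidation genes (0.16, 0.00031; adjusted p = 0.58 with an estimated correlation). Without control sham replicate 3 the first changed direction and lost its call (0.845), and the others lost it (0.183 and 0.0543). Calcineurin genes also lost it without control sham replicate 2 (0.277) or knockout sham replicate 2 (0.1097) or 3 (0.0613) or with the length and GC trend removed (0.0516), and fatty acid oxidation without knockout sham replicate 1 (0.108). Lower were fibroblast markers (−0.11, 0.010), smooth muscle markers (−0.21, 0.0043) and inflammatory genes (−0.08, 0.010), each with adjusted p = 0.58 with an estimated correlation, macrophage markers (−0.13, 0.0050; adjusted p = 0.70 with an estimated correlation) and immediate early genes (−0.22, 0.010; adjusted p = 0.81 with an estimated correlation). Fibroblast markers lost the call without control sham replicate 1 (0.163) or 3 (0.0998), smooth muscle markers without control sham replicate 3 (0.133) and macrophage markers without control sham replicate 2 (0.252). Inflammatory genes lost it without control sham replicate 2 (0.215) or knockout sham replicate 1 (0.0547) or 2 (0.0558), and immediate early genes without control sham replicate 2 (0.215) or 3 (0.254) or knockout sham replicate 1 (0.473).

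After TAC, immediate early genes were lower in knockouts (−0.46, 0.0059; adjusted p = 0.79 with an estimated correlation), 1 of them by either adjustment, a call that ended without control TAC replicate 1 (0.0688) or 2 (0.569) or knockout TAC replicate 3 (0.0501). With TAC in knockouts, immediate early genes (0.25, 0.010; adjusted p = 0.81 with an estimated correlation) and heat shock genes (0.29, 0.0073; adjusted p = 0.70 with an estimated correlation) were higher; the first call ended without knockout sham replicate 1 (0.406) or knockout TAC replicate 2 (0.0542), the second without knockout TAC replicate 3 (0.0503). In the difference of TAC effects, fatty acid oxidation (0.17, 0.028; adjusted p = 0.77 with an estimated correlation) lost its call without control sham replicate 1 (0.1595) or 2 (0.1397), knockout sham replicate 2 (0.0702) or 3 (0.0879), control TAC replicate 2 (0.143) or knockout TAC replicate 1 (0.0796), and the calcineurin list (−0.27, 0.022; adjusted p = 0.58 with an estimated correlation) without control sham replicate 2 (0.0753). Both calls ended with the length and GC trend removed (medians 0.10 and −0.08, adjusted p = 0.11 and 0.38).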
